A study of Homo sapiens with 10 samples.

How the data were processed

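Bulk RNA sequencing was done on 10 samples of H9 cells, a widely used human embryonic stem cell line, along a neural differentiation. Per the labels, 5 samples came from wild-type cells (Ctrl) and 5 from cells labelled SOX1-OT V1 PAKI (V1PAKI here), with 1 library per line at each of 5 stages: d0, d4, d10, d16D and d16V. The labels spell out neither PAKI nor the letters D and V. Per the labels' protocols, colonies were grown as embryoid bodies in suspension, received a neural medium from day 4 and were attached at day 7, and an arm for ventral telencephalon received Sonic hedgehog protein and SAG, an agonist of the same pathway, from day 10. RNA was taken up in Trizol and made into libraries with the TruSeq RNA kit, per the labels' protocols.

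The authors deposited FPKM values (fragments scaled by transcript length and library total) for 42335 gene symbols in each of the 10 libraries. The tools named, per the submitters' processing notes, are cutadapt 1.18, HISAT2 2.1.0 and Cufflinks, with genome build GRCh38. The annotation, any filter and the treatment of strand are not given in the sources used here, so a gene and its antisense partner, such as LHX5 and LHX5-AS1, cannot be told apart with certainty. FPKM summed to between 200509 and 256270 per library. Low values showed no steps of whole reads, so the sequencing depth of each library is unknown and neither counting intervals nor detection floors could be given. Between 10193 and 15177 genes were listed at 0 in a library. A value of 0 can also be a failed estimate of the upstream tool, as the on and off pattern of read-through genes such as TMEM189-UBE2V1 shows, so such genes are described only as listed at 0. No pair of libraries held the same values. All 10 columns were matched to a sample by name.

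Values were analysed as log2(FPKM + 1), with a pseudocount of 1, so differences understate the change of genes with low values. The 15779 genes with at least 1 FPKM in at least 2 libraries were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), with stage and genotype as terms and 4 residual degrees of freedom, or 7.77 after moderation. This fit gave the genotype effect over the 5 stages, with the stages as blocks, and 5 stage changes, with genotype as a block. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. No stage held more than 1 library of a line and nothing in the labels marks separate cultures. The p-values therefore measure the spread between stages or between the lines, which includes any effect of genotype that differs between stages, and not the spread between repeated cultures. Both day 16 libraries of a line may share a culture up to day 10. V1PAKI was compared with Ctrl at each stage without a test, by counting genes that differed by at least 1 on the log2 scale among genes with at least 1 FPKM in either library.

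For SOX1-OT, SOX1 and HDAC10, the transcripts in the study's title, the 5 stage differences were tested with an exact two-sided sign-flip permutation test, whose smallest possible p is 0.0625. Coordinates came from a GRCh38 gene annotation, which matched 39994 symbols directly and 169 through an older symbol. The files hold 1 value for SOX1-OT, so its V1 transcript could not be separated from others.

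Gene lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The 27 lists hold 458 genes, 454 of them in the table. They cover pluripotency, neural progenitor, anterior forebrain, dorsal telencephalon, ventral telencephalon, hedgehog response, neuron, Notch and proneural, midbrain with hindbrain and spinal cord, retina with eye field and choroid plexus, mesoderm, endoderm, trophoblast and amnion, non-neural ectoderm and epithelium, neural crest, fibroblast with muscle and mesenchyme, endothelium and blood, proliferation, p53 response, hypoxia and glycolysis, stress and immediate early, histone deacetylases, the SOX family, the SOX1 neighbourhood on chromosome 13, WNT with BMP and TGF beta response, imprinted genes and mitochondrially encoded oxidative phosphorylation. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation as the alternative, and with fry, all adjusted over the 27 lists. Brackets on a list give its measured members, its members called over all genes and adjusted over the list alone, its median log2 change, and the adjusted p of camera with the preset and with the estimated correlation. Brackets on a gene give the log2 change, its standard error and the adjusted p. At a single stage a list of at least 3 members was described by its median log2 difference and the percentile of that median among 10000 random lists matched on size and mean expression in 20 bins, which describes these libraries only. Genes named in the text were SOX1-OT, SOX1 and HDAC10; the 6 highest and 6 lowest changes that passed in each test and went the same way in every pair; the 6 highest and 6 lowest differences per stage; the 4 members of each list with the largest change; and members of the pluripotency, neural progenitor, neuron, ventral telencephalon and hedgehog lists. Unnamed, clone-based, pseudogene (by a name ending in P and a number), ribosomal protein, small RNA and haemoglobin genes were passed over in the first parts of the rule. Exceptions are marked as chosen after their values were seen. Some genes that the rule selects are not reported here.

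The fit was tested on simulated data for the 15779 genes, with fitted stage means, independent normal noise at the moderated spread and 200 genes changed. Correlation between genes was left out, so the shares recovered describe the simulation and not the power of the real fit. For the genotype effect it recovered 83% of 100 genes changed by 1 on the log2 scale and 98% of 100 changed by 2, with 14 unchanged genes called. For d4 against d0, where both stages were first set to each gene's mean over the stages, it recovered 18% and 89%, with 4 unchanged genes called.

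Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, FPKM rescaled to the same total in each library (TPM), median-of-ratios scaling, quantile normalization, no intensity trend, no block, both day 16 arms averaged, and each library or stage left out of the fits in turn. Removal of each library's trend on transcript GC content and length (splines with 5 degrees of freedom, available for 15578 of the 15779 genes, 98.7%), leaving out chromosome 17 at d0, and leaving each stage out of the means of SOX1-OT, SOX1 and HDAC10 were added after the data were seen. Other groupings of the 10 libraries were drawn as 100 of 126 possible splits. No level of any gene used to infer sex is reported.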

Results

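SOX1, a transcription factor of early neural progenitors, was lower in V1PAKI than in Ctrl at both day 16 arms, at 10.9 against 32.6 FPKM at d16D (2.98-fold) and 7.38 against 18.7 FPKM at d16V (2.53-fold). SOX1-OT, a noncoding gene on chromosome 13, was lower as well, at 0.212 against 1.87 FPKM at d16D and 1.22 against 3.51 FPKM at d16V. In the annotation used for coordinates its 1 transcript model starts 36.6 kb after the end of SOX1. The annotation behind the FPKM values is not given, so the stretch they measure as SOX1-OT, and its distance to SOX1, are unknown. At d10 SOX1 stood at 0.306 FPKM in V1PAKI and 1.26 in Ctrl, and at d0 and d4 both genes lay below 0.1 FPKM in both lines. HDAC10, a histone deacetylase, was at 1.98 against 1.10 FPKM at d0, 2.68 against 2.74 at d4, 1.05 against 2.49 at d10, 3.18 against 3.92 at d16D and 3.91 against 4.12 at d16V. Over the 5 stages the mean log2 difference (V1PAKI minus Ctrl) was -0.46 (SD 0.62) for SOX1-OT, -0.69 (SD 0.71) for SOX1 and -0.12 (SD 0.46) for HDAC10, with V1PAKI lower in 3, 3 and 4 of 5 pairs. For SOX1-OT and SOX1 the d0 and d4 pairs, below 0.1 FPKM in both lines, say little about direction. The exact sign-flip test gave p = 0.25 for SOX1-OT, 0.25 for SOX1 and 0.5625 for HDAC10 (adjusted p = 0.375, 0.375 and 0.5625). With 5 pairs its smallest possible p lies above the threshold, so no gene could pass and the test cannot decide for or against a difference. The HDAC10 mean turned to 0.05 without d10 and stood at -0.02 without the GC and length trend. With stages left out in turn, the mean of SOX1 lay between -0.88 and -0.49 and that of SOX1-OT between -0.57 and -0.26. The SOX1-OT mean was -0.84 with a pseudocount of 0.1 and -0.72 with TPM.

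Over the 5 stages, 3 genes were lower in V1PAKI and no gene was higher. With 1 line per genotype, an effect of the edit on them could not be separated from the line's history. ZNF558 (-1.89 on the log2 scale, SE 0.15, adjusted p = 0.0140) and ZNF542P (-1.86, SE 0.15, adjusted p = 0.0140), both zinc finger genes on chromosome 19, were listed at 0 in all 5 V1PAKI libraries and lay between 1.89 and 3.91 FPKM in Ctrl. ZNF619, a zinc finger gene on chromosome 3, stood at -1.46 (SE 0.12, adjusted p = 0.0152) and was lower in 5 of 5 pairs. Among genes chosen after their values were seen, none passed: NLRP2, a gene linked to early embryos and imprinting, was at 26.8 FPKM in Ctrl and 0.143 in V1PAKI at d0 and 3.26 and 0 at d16V (-3.17, SE 0.38, adjusted p = 0.137). Lower values over the stages were also seen for SYT11 (-1.68, adjusted p = 0.137), ZNF880 (-1.01, 0.244) and CDK10 (-1.40, 0.257). Of 505 genes with zinc finger names, 23 were lower and 1 was higher at an unadjusted p below 0.05.

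No member of any list passed for genotype, either over all genes or adjusted over the list alone. In the Notch and proneural list, whose genes time the birth of neurons, 4 of 18 measured members were above 0 (median -0.22, camera adjusted p = 0.00887, but adjusted p = 0.989 with an estimated correlation). Among them were HES5 at -0.72 (SE 0.33), INSM1 at -0.54 (SE 0.19) and DLL1 at -0.41 (SE 0.22). In the ventral telencephalon list 1 of 14 was above 0 (median -0.10, camera adjusted p = 0.0449, but 0.989 with an estimated correlation). DLX1 was at -0.80 (SE 0.45) and DLX5 at -0.79 (SE 0.25). TUBB3, a neuronal tubulin, was at -0.65 (SE 0.24), ID1 at -0.82 (SE 0.39) and NKX2-5 at 0.75 (SE 0.24). For the other lists the median and the camera adjusted p were: neural progenitor -0.04 and 0.248, anterior forebrain -0.06 and 0.601, dorsal telencephalon -0.15 and 0.123, and hedgehog response 0.03 and 0.601. They were neuron -0.12 and 0.123, midbrain and hindbrain 0.03 and 0.825, retina and eye field -0.02 and 0.852, and pluripotency 0.13 and 0.152. Outside the nervous system they were mesoderm -0.09 and 0.859, endoderm -0.26 and 0.825, trophoblast -0.09 and 0.596, non-neural ectoderm -0.15 and 0.248, neural crest -0.06 and 0.825, mesenchyme -0.16 and 0.790, and endothelium -0.03 and 0.852. Lists of pathways and families stood at -0.01 and 0.859 for proliferation, -0.00 and 0.790 for p53 response, 0.03 and 0.123 for hypoxia, -0.11 and 0.152 for stress, -0.10 and 0.248 for histone deacetylases, 0.00 and 0.825 for the SOX family, -0.02 and 0.601 for the SOX1 neighbourhood, -0.07 and 0.224 for WNT and BMP response, -0.11 and 0.152 for imprinted genes, and -0.01 and 0.976 for mitochondrially encoded oxidative phosphorylation.

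The 3 genes were the only calls of limma among 15779 at the adjusted threshold, with 161 genes higher and 229 lower at an unadjusted p below 0.05, and fry called 0 lists. The unadjusted counts were 200 higher and 190 lower with median-of-ratios scaling, and 304 and 293 without the GC and length trend, so the excess of lower genes depended on the setting. Leaving out d4, d10, d16D or d16V gave 0 genes each, as did no filter, a filter at 5 FPKM and averaging both day 16 arms.

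Between d0 and d4 LHX5 and SIX3 of the forebrain rose while the FGF target DUSP6 fell in both lines. LHX5, a homeobox gene of the early forebrain, rose from 0 and 0.0295 FPKM (Ctrl and V1PAKI) to 20.6 and 10.5 (log2 change 3.96, SE 0.35, adjusted p = 0.0139), with its neighbour LHX5-AS1 (3.77, SE 0.45, 0.0240) and SIX3, a gene of the anterior neural plate (3.34, SE 0.53, 0.0438). Other genes that rose were MAGEB17 (4.36, SE 0.70, 0.0445), CYP26A1, which breaks down retinoic acid (3.75, SE 0.45, 0.0240), FAM20A (3.56, SE 0.51, 0.0371) and SOX21 (3.47, SE 0.40, 0.0240). DUSP6, a target of FGF and MAP kinase signalling, fell from 60.1 and 83.9 FPKM to 1.57 and 1.05 (-4.97, SE 0.30, 0.00349). Falls were also seen for FGFBP3 (-2.99, SE 0.42, 0.0370), P2RY1 (-2.80, SE 0.24, 0.0139), NPTX1 (-2.53, SE 0.33, 0.0302), VSNL1 (-2.46, SE 0.26, 0.0172), RIPOR2 (-2.3, SE 0.31, 0.0345) and THY1, a surface protein (-1.70, SE 0.22, 0.0302). The hedgehog receptor and target PTCH1 rose by 2.04 (SE 0.22, 0.0205), FGF8 by 1.52 (SE 0.22, 0.0371), ID4 by 2.78 (SE 0.34, 0.0264), and DLK1, an imprinted gene, by 2.39 (SE 0.32, 0.0306).

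TFAP2C (2.46, SE 0.38, adjusted p = 0.0384), GRHL3 (2.68, SE 0.45, 0.0489) and BMP7 (1.37, SE 0.22, 0.0454) rose too. By lists, camera placed WNT and BMP response higher (18 measured, 1 rose and 6 adjusted over the list alone, median 0.80, adjusted p = 0.000191, but 0.781 with an estimated correlation). Pluripotency was also higher (20 measured, 0 and 4, 0.44, 0.000389, estimated 0.781), where UTF1 was at 2.96 (adjusted p = 0.0657) and LEFTY1 at 2.41 (0.0712) without passing. Endoderm (17 measured, 0 and 2, 1.11, 0.000696, estimated 0.798), anterior forebrain (17 measured, 2 and 4 with 1 fall, 0.69, 0.00162, estimated 0.728) and non-neural ectoderm (13 measured, 2 and 3, 0.58, 0.00162, estimated 0.798) were also higher. The same held for hedgehog response (13 measured, 1 and 3, 0.29, 0.00493, estimated 0.746) and retina and eye field (9 measured, 0 and 3, 0.40, 0.00493, estimated 0.728). Trophoblast (14 measured, 0 and 0, 0.42, 0.0243, estimated 0.798) and midbrain and hindbrain (10 measured, 1 and 2, 0.21, 0.0323, estimated 0.798) followed. Hypoxia (16 measured, median -0.42, 0.0226, estimated 0.798) and neuron (22 measured, -0.21, 0.0323, estimated 0.798) were lower, with no member passing either way of adjusting. Of these 11 lists fry called 0. In limma 80 genes rose and 49 fell, against 114 and 108 without the GC and length trend. The count of 129 became 0 without Ctrl d0, 0 without V1PAKI d0, 1 without Ctrl d4 and 2 without V1PAKI d4 (1870 genes at an unadjusted p below 0.05). No filter gave 11 genes, a filter at 5 FPKM 59, TPM 79 and no block for genotype 237.

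From d4 to d10 4 of 20 pluripotency genes fell and 8 of 24 neural progenitor genes rose. DPPA3 (-2.23, SE 0.22, adjusted p = 0.0137), UTF1 (-3.20, SE 0.55, 0.0427), DNMT3B, a DNA methyltransferase (-1.66, SE 0.30, 0.0459), DPPA4 (-1.34, SE 0.20, 0.0329) and DPPA2 (-1.19, SE 0.22, 0.0496) fell. POU5F1 was at -1.68 (SE 0.76, 0.349) and NANOG at -1.59 (SE 0.38, 0.0913) without passing. LHX2, a homeobox gene of eye and cortex (4.08, SE 0.55, 0.0229), NR2F1 (3.0, SE 0.20, 0.00890) and the eye field genes RAX (3.18, SE 0.30, 0.0127) and SIX6 (3.11, SE 0.33, 0.0139) rose. So did the neural cadherin CDH2 (2.83, SE 0.32, 0.0163), LIX1 (2.44, SE 0.40, 0.0405) and PAX6, a master gene of eye and cortex (1.43, SE 0.26, 0.0459). FGF8 (2.44, SE 0.22, 0.0125), PAX2 (2.60, SE 0.30, 0.0166) and PAX8 (1.49, SE 0.21, 0.0287), all active at the midbrain and hindbrain border, rose as well.

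Among the largest rises were ANKRD1 (4.64, SE 0.56, adjusted p = 0.0167), the smooth muscle actin ACTA2 (4.13, SE 0.49, 0.0166) and the placental hormone subunit CGA (4.01, SE 0.30, 0.00940). The same direction was seen for DLK1 (3.97, SE 0.32, 0.0102), TGM2 (3.93, SE 0.48, 0.0167) and FBN1 (1.87, SE 0.24, 0.0206). ADRA2A (-2.88, SE 0.35, 0.0167), GUCA1A (-2.40, SE 0.36, 0.0312), LNCPRESS2 (-2.40, SE 0.34, 0.0286) and LDHD (-2.19, SE 0.34, 0.0350) fell. COL3A1, a fibrillar collagen, was at 4.16 (SE 1.56, 0.262) and HAND1 at 3.81 (SE 1.45, 0.270), neither passing.

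In camera the pluripotency list was lower (20 measured, 4 fell and 14 adjusted over the list alone, median -1.63, adjusted p = 5.26e-13, but 0.210 with an estimated correlation). Mitochondrially encoded oxidative phosphorylation was lower as well (13 measured, 0 and 0, -0.43, 0.000104, estimated 0.388). Higher lists were neural progenitor (24 measured, 8 and 14, 1.23, 4.74e-12, estimated 0.157), anterior forebrain (17 measured, 4 and 6, 0.79, 6.00e-08, estimated 0.157) and midbrain and hindbrain (10 measured, 3 and 4, 1.31, 2.00e-06, estimated 0.223). Retina and eye field (9 measured, 3 and 3, 0.67, 0.000431, estimated 0.157) and dorsal telencephalon (15 measured, 1 and 3, 0.38, 0.00403, estimated 0.242) joined them. Non-neural lists were higher too: trophoblast (14 measured, 1 and 6, 1.11, 5.03e-08, estimated 0.384), mesenchyme (18 measured, 2 and 2, 1.78, 8.31e-06, estimated 0.541) and mesoderm (16 measured, 0 and 0, 0.82, 0.00490, estimated 0.743). Imprinted genes (14 measured, 3 and 6 with 1 fall, 1.28, 4.09e-07, estimated 0.157) and the SOX family (15 measured, 0 and 2, 0.69, 0.0388, estimated 0.242) completed the 12 lists, and fry called 6. In limma 145 genes rose and 82 fell, against 277 and 38 with TPM, 183 and 33 with a pseudocount of 0.1 and 309 and 320 without the GC and length trend. The count of 227 became 0 without Ctrl d4, 0 without V1PAKI d4, 124 without Ctrl d10 and 0 without V1PAKI d10. It was 3 with no filter and 408 with no block for genotype.

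By d16D 7 of 15 dorsal telencephalon genes and 6 of 18 Notch and proneural genes had risen against d10. EMX2, a homeobox gene of the dorsal cortex (3.53, SE 0.26, adjusted p = 0.00359), the cortical hem ligand WNT8B (3.51, SE 0.48, 0.0229) and FEZF2 (3.41, SE 0.23, 0.00359) rose in both lines. DMRTA2 (3.05, SE 0.29, 0.00605), WNT7B (2.80, SE 0.31, 0.0110) and NEUROG1, a proneural factor (2.44, SE 0.23, 0.00654), rose with them. SOX1 rose by 3.54 (SE 0.40, 0.0113), ZIC1 by 3.33 (SE 0.33, 0.00732), POU3F3 by 3.82 (SE 0.64, 0.0467), SOX3 by 2.40 (SE 0.37, 0.0350) and the Notch target HES5 by 3.92 (SE 0.53, 0.0218). Some neuronal genes rose as well, among them NHLH1 (2.84, SE 0.24, 0.00465), the neurofilament NEFM (2.71, SE 0.23, 0.00465), ELAVL3 (2.59, SE 0.41, 0.0395) and SYT4 (1.68, SE 0.24, 0.0256). INSM1 (2.38, SE 0.30, 0.0156) and the neuropeptide gene TRH (3.85, SE 0.26, 0.00359) rose too. Among the largest falls were ANKRD1 (-4.25, SE 0.56, 0.0189), NPPB (-3.96, SE 0.44, 0.0113), CGA (-3.71, SE 0.30, 0.00465), TGM2 (-3.19, SE 0.48, 0.0339) and ACTA1 (-3.11, SE 0.48, 0.0355). PRDM14 (-2.88, SE 0.41, 0.0256), DNMT3B (-2.3, SE 0.30, 0.0179), DPPA4 (-1.55, SE 0.20, 0.0185) and LIN28A (-1.52, SE 0.19, 0.0168) of the pluripotency list fell. The liver genes ALB (3.50, SE 0.42, 0.0140) and AFP (4.12, SE 1.36, 0.191, not passing) were higher.

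Camera placed the dorsal telencephalon list higher (15 measured, 7 rose and 11 adjusted over the list alone, median 1.40, adjusted p = 3.62e-11, but 0.163 with an estimated correlation). Beside it were neuron (22 measured, 4 and 15, 1.05, 3.62e-11, estimated 0.30), Notch and proneural (18 measured, 6 and 12, 1.30, 4.69e-10, estimated 0.248) and neural progenitor (24 measured, 6 and 12, 1.19, 2.30e-07, estimated 0.294). Smaller shifts upward were found for ventral telencephalon (14 measured, 1 and 4, 0.47, 0.00124, estimated 0.386) and anterior forebrain (17 measured, 4 and 6 with 1 fall, 0.40, 0.00431, estimated 0.30). The SOX family (15 measured, 2 and 4, 0.68, 0.00627, estimated 0.248), neural crest (18 measured, 1 and 2, 0.42, 0.0238, estimated 0.715) and endoderm (17 measured, 1 and 2, 0.77, 0.0262, estimated 0.839) were higher too. Lower were pluripotency (20 measured, 4 and 14, -1.49, 1.50e-13, estimated 0.248) and mitochondrially encoded oxidative phosphorylation (13 measured, 0 and 0, -0.50, 5.27e-06, estimated 0.343). Trophoblast (14 measured, 1 and 4, -0.87, 0.00190, estimated 0.666), proliferation (20 measured, 0 and 0, -0.31, 0.00329, estimated 0.648) and hypoxia (16 measured, 0 and 0, -0.39, 0.0141, estimated 0.715) were lower as well. These changes pool both lines, which differed for non-neural genes. Over 47 mesoderm, endoderm and mesenchyme genes the median log2 level fell in Ctrl (3.4 to 1.67) and rose in V1PAKI (1.83 to 3.22). The median difference, V1PAKI minus Ctrl, went from -1.22 at d10 to 1.56 at d16D for endoderm. It went from -0.319 to 1.02 for neural crest and from -1.004 to 1.49 for trophoblast. Among the lists fry called 8. In limma 87 genes rose and 60 fell, against 150 and 183 without the GC and length trend and 34 and 48 with a filter at 5 FPKM. The count of 147 became 29 without Ctrl d10, 94 without Ctrl d16D, 31 without V1PAKI d10 and 384 without V1PAKI d16D. No filter gave 34, a pseudocount of 0.1 91 and no block for genotype 244.

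At d16V 5 of 14 ventral telencephalon genes and 6 of 13 hedgehog response genes had risen against d10. NKX2-1, a homeobox gene of the ventral forebrain, rose from 0 and 0.0285 FPKM in Ctrl and V1PAKI to 67.5 and 44.8 (5.79, SE 0.23, adjusted p = 0.000104). It was joined by NKX2-8 (4.57, SE 0.27, 0.000854), NKX2-2 (4.46, SE 0.18, 0.000104), DBX1 (3.8, SE 0.24, 0.00112), OLIG1 (3.49, SE 0.40, 0.0107) and NKX6-2 (3.24, SE 0.39, 0.0145). The hedgehog targets PTCH1 (3.01, SE 0.22, 0.00201) and HHIP (2.15, SE 0.22, 0.00741) and the ligand SHH (2.85, SE 0.36, 0.0171) rose. HES5 rose by 3.81 (SE 0.53, 0.0222), SOX3 by 2.92 (SE 0.37, 0.0164) and SOX1 by 2.90 (SE 0.40, 0.0222). FGFBP3 rose by 3.75 (SE 0.42, 0.0103), SYT4 by 2.97 (SE 0.24, 0.00266), PLAGL1 by 2.36 (SE 0.27, 0.0107) and NES by 1.63 (SE 0.26, 0.0397). The cardiac actin ACTC1 (-6.01, SE 0.88, 0.0304), NPPB (-4.33, SE 0.44, 0.00718), CGA (-4.09, SE 0.30, 0.00201), and ANKRD1 (-3.96, SE 0.56, 0.0245) fell. TGM2 (-3.78, SE 0.48, 0.0171), the simple keratin KRT7 (-3.07, SE 0.46, 0.0341) and PRDM14 (-3.09, SE 0.41, 0.0195) fell too.

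Of 13 measured hedgehog response genes 6 rose (8 adjusted over the list alone, median 2.08, camera adjusted p = 2.78e-09, but 0.237 with an estimated correlation). Of 14 ventral telencephalon genes 5 rose (10 alone, 1.90, 2.78e-09, estimated 0.249). Higher in camera were also neuron (22 measured, 3 and 16 alone, 1.06, 5.32e-11, estimated 0.328), Notch and proneural (18 measured, 3 and 10, 0.86, 5.36e-08, estimated 0.249) and neural progenitor (24 measured, 6 and 12 with 2 falls, 0.69, 5.03e-05, estimated 0.328). So were the SOX family (15 measured, 3 and 6, 0.84, 0.000311, estimated 0.237), anterior forebrain (17 measured, 2 and 4, 0.46, 0.0108, estimated 0.328) and imprinted genes (14 measured, 1 and 6 with 1 fall, 0.47, 0.0150, estimated 0.328). Pluripotency was lower (20 measured, 3 and 16, -1.71, 3.21e-12, estimated 0.249), with trophoblast (14 measured, 2 and 9, -1.65, 5.36e-08, estimated 0.363). Mesenchyme (18 measured, 1 rise over all genes, 1 rise and 3 falls alone, -1.71, 5.48e-05, estimated 0.463), non-neural ectoderm (13 measured, 0 and 6, -1.74, 6.88e-05, estimated 0.442) and mesoderm (16 measured, 0 and 0, -1.0, 0.000279, estimated 0.482) were lower. Smaller shifts downward were those of mitochondrially encoded oxidative phosphorylation (13 measured, 0 and 0, -0.41, 0.000209, estimated 0.393), hypoxia (16 measured, 0 and 6, -0.60, 0.000966, estimated 0.463) and WNT and BMP response (18 measured, 1 and 2, -0.50, 0.00105, estimated 0.463). Among the lists fry called 7. In limma 82 genes rose and 46 fell, against 87 and 85 without the GC and length trend, 43 and 43 with a filter at 5 FPKM and 50 and 14 with no filter. The count of 128 became 24 without Ctrl d10, 16 without Ctrl d16V, 55 without V1PAKI d10 and 30 without V1PAKI d16V. Quantile normalization gave 194 and no block for genotype 277.

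Directly between the day 16 arms, d16V held more NKX2 and hedgehog response transcripts and less EMX2 than d16D in both lines. NKX2-1 (5.74, SE 0.23, adjusted p = 8.79e-05), NKX2-2 (4.56, SE 0.18, 8.79e-05), NKX2-8 (4.52, SE 0.27, 0.00123), SFTA3 (3.39, SE 0.22, 0.00180), FOXD1 (2.91, SE 0.29, 0.0117) and NKX6-2 (2.88, SE 0.39, 0.0369) rose. PTCH1 went from 5.56 and 8.04 FPKM (Ctrl and V1PAKI) to 65.3 and 73.2 (3.19, SE 0.22, 0.00222). SHH (2.62, SE 0.36, 0.0369), the effector GLI1 (2.44, SE 0.36, 0.0492), HHIP (2.1, SE 0.22, 0.0133) and NKX6-1 (1.84, SE 0.19, 0.0117) rose with it. EMX2 fell from 24.2 and 12.3 FPKM to 1.64 and 1.40 (-2.86, SE 0.26, 0.00954). Falls were shared by EMX2OS (-2.73, SE 0.33, 0.0219), TRH (-3.67, SE 0.26, 0.00222), RSPO1 (-2.81, SE 0.30, 0.0133), DMRTA2 (-2.59, SE 0.29, 0.0145), WNT7B (-2.43, SE 0.31, 0.0280) and NEUROG1 (-1.92, SE 0.23, 0.0231). SOX1 was at -0.64 (SE 0.40, adjusted p = 1), WNT8B at -2.82 (SE 0.48, 0.0895) and OLIG1 at 2.55 (SE 0.40, 0.0629), none passing. Other ventral telencephalon genes were lower at d16V in Ctrl, with GSX2 at 0.924 against 9.16 FPKM, DLX1 at 6.62 against 16.2 and DLX2 at 5.05 against 12.1, and in Ctrl 5 of 15 measured members were at least 2-fold higher and 4 lower. In V1PAKI they were higher at d16V, with GSX2 at 0.809 against 0.130, DLX1 at 4.10 against 0.882 and DLX2 at 3.15 against 1.96, and 7 of 13 measured members were at least 2-fold higher and 1 lower.

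**Figure D1:**
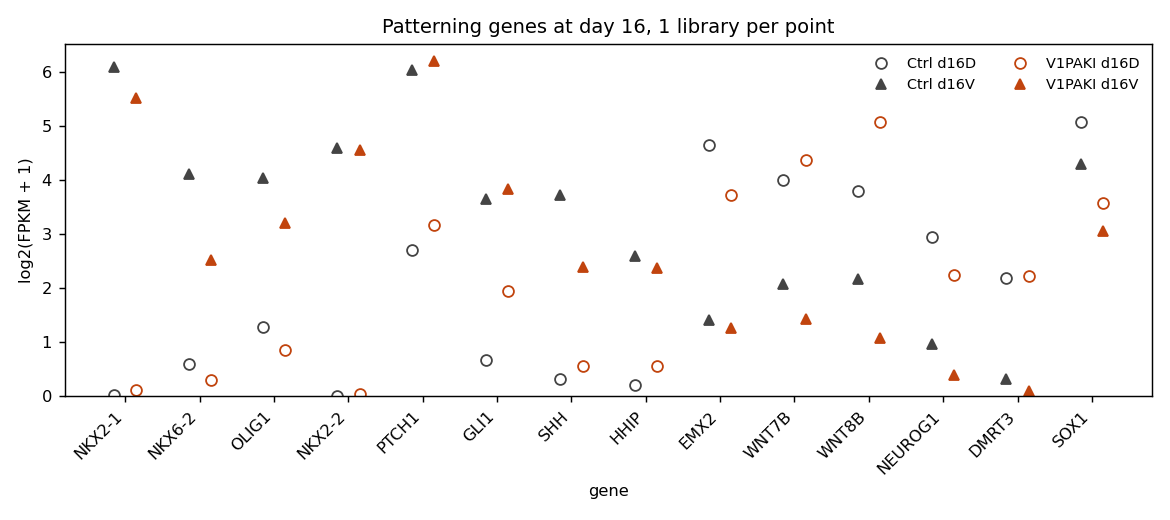
Log2(FPKM + 1) of dorsal, ventral and hedgehog response genes in the day 16 libraries of Ctrl and V1PAKI. NKX2-1 rose by 5.74 from d16D to d16V and EMX2 fell by 2.86, on the log2 scale.

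Of 15 measured dorsal telencephalon genes 3 fell and 1 rose (12 and 2 adjusted over the list alone, median -1.24, camera adjusted p = 5.11e-16, but 0.0773 with an estimated correlation). Of 13 hedgehog response genes 7 rose (8 with 2 falls alone, 1.84, 3.04e-12, estimated 0.0881). Ventral telencephalon (14 measured, 2 and 6 with 1 fall, 0.54, 9.43e-08, estimated 0.361), imprinted genes (14 measured, 0 and 0, 0.25, 0.0213, estimated 0.439) and proliferation (20 measured, 0 and 0, 0.21, 0.0231, estimated 0.595) were higher. Lower were WNT and BMP response (18 measured, 0 and 4, -0.85, 4.05e-10, estimated 0.439), neural crest (18 measured, 0 and 2, -1.03, 3.06e-08, estimated 0.439) and endoderm (17 measured, 0 and 7 with 2 rises, -1.45, 1.39e-06, estimated 0.487). Non-neural ectoderm (13 measured, 0 and 0, -1.29, 6.18e-06, estimated 0.487) and mesenchyme (18 measured, 0 and 0, -0.92, 8.59e-06, estimated 0.487) were lower, as were trophoblast (14 measured, 0 and 0, -0.89, 1.31e-05, estimated 0.487), mesoderm (16 measured, 0 and 0, -0.82, 1.39e-05, estimated 0.487) and endothelium (6 measured, 0 and 1, -1.05, 0.0213, estimated 0.487). Medians within each line, given without a test, cover members with at least 1 FPKM in either arm of that line, so the sets differ between the lines. The hedgehog response median was 2.17 in Ctrl and 1.70 in V1PAKI, the dorsal median -1.63 and -1.51, the ventral median 0.24 and 1.31, and the endoderm median -0.47 and -3.22. Among medians of opposite sign in Ctrl and V1PAKI were those of mesoderm (0.24 and -1.94), non-neural ectoderm (0.30 and -2.83), mesenchyme (0.58 and -2.09) and endothelium (0.31 and -1.87). WNT and BMP response (-0.13 and -1.36), neural crest (-0.16 and -1.85) and trophoblast (-0.10 and -2.11) were lower mainly in V1PAKI. Among the lists fry called 2. In limma 31 genes rose and 26 fell, against 25 and 33 without the GC and length trend. The count of 57 became 101 without Ctrl d16D, 5 without Ctrl d16V, 30 without V1PAKI d16D and 9 without V1PAKI d16V. It was 7 with a pseudocount of 0.1, 2 with a filter at 5 FPKM and 18 with TPM.

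At d0 pluripotency genes were similar in both lines (20 measured, 0 beyond 2-fold, median log2 difference 0.02, percentile 16 among random lists, and -0.13 with median-of-ratios scaling). DNMT3B stood at 237 FPKM in V1PAKI against 400.3 in Ctrl, TDGF1 at 146 against 239 and PRDM14 at 14.0 against 25.0. Higher in V1PAKI were TCEAL5 (13 against 0.294 FPKM), SCGB3A2 (28.4 against 2.51) and NDUFA1, a subunit of respiratory complex I (56.0 against 7.51). NLRP2 (0.143 against 26.8), TOMM6, a part of the mitochondrial import pore (2.75 against 84.5), MCCC2 (0.0705 against 21.2), CEBPZOS (0.286 against 13.4) and OCIAD1-AS1 (0.182 against 6.88) were lower. For several of these the Ctrl d0 library stood apart. NDUFA1 lay between 44.9 and 64.7 FPKM in all other libraries but V1PAKI d10 (12.5), and outside Ctrl d0 the highest value was 7.14 for TOMM6, 3.54 for MCCC2, 0.922 for CEBPZOS and 0.983 for OCIAD1-AS1. PEG3, an imprinted gene, was listed at 0 in V1PAKI and at 5.33 FPKM in Ctrl, and lay at or near 0 in the later libraries of both lines. Other list members that differed included STMN2 (7.14 against 1.2), DLL3 (10.9 against 3.13), NGFR (9.25 against 2.17), ASNS (15.2 against 43.7) and MKI67 (9.72 against 20.9). These genes were named without regard to position, so some may lie in the chromosome segments described below, which differed at d0. The proliferation list as a whole centred at 0.01 (20 measured, 0 at least 2-fold higher and 1 lower). Histone deacetylases (15 measured, 0 beyond 2-fold, median 0.31, percentile 95.5) and the SOX family (10 measured, 1 beyond 2-fold, 0.49, percentile 98.4) had medians above 0, as had mesoderm (3 measured, 1.01, percentile 99.1), ventral telencephalon (3 measured, 1.06, percentile 98.4), Notch and proneural (11 measured, 0.39, percentile 97.8) and neural progenitor (12 measured, 0.32, percentile 95.6). The median of all genes stood at 0.098. Over all fitted members the medians were 0.27 for histone deacetylases, 0.19 for the SOX family, 0.05 for mesoderm, 0 for ventral telencephalon, 0 for Notch and proneural and 0.04 for neural progenitor. Without the GC and length trend they were 0.14, 0.09, -0.13, -0.14, -0.20 and -0.03.

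On chromosome 17, genes beyond 40 Mb were higher in V1PAKI at d0 in every 10 Mb bin once the GC and length trend was removed. Their medians ran from 0.36 to 0.50, against -0.10 to -0.0033 before 40 Mb, and at the other stages the bins lay between -0.13 and 0.10. On chromosome 10, 39 of 41 genes from 120 to 130 Mb were lower at d0 (median -0.85), as were 25 of 27 beyond (-0.50). At the other stages these bins lay between -0.12 and 0.15. In all, 621 of 13661 genes differed at least 2-fold at d0, 509 higher and 112 lower. The split moved to 227 higher and 157 lower after removal of the GC and length trend, 728 and 319 with TPM, 336 and 164 with median-of-ratios scaling and 319 and 158 with quantile normalization, and without chromosome 17 it was 416 and 105. BLOC1S5-TXNDC5, SYS1-DBNDD2 and TMEM189-UBE2V1, also among the highest, are read-through names that share reads with their neighbours, so their values are uncertain.

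**Figure D2:**
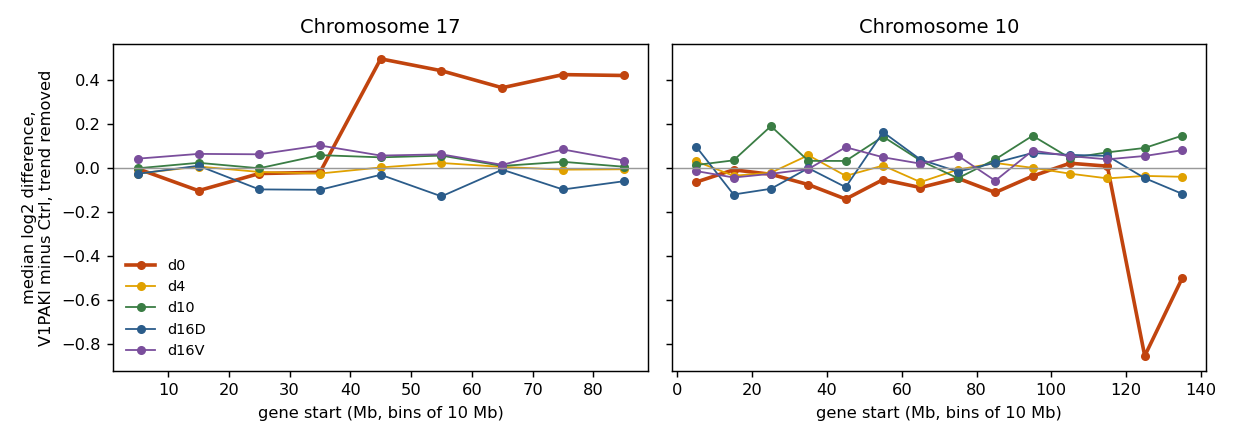
Median log2 difference (V1PAKI minus Ctrl) of genes in 10 Mb bins along chromosomes 17 and 10, by stage, after removal of the GC and length trend. At d0 the bin from 120 to 130 Mb of chromosome 10 stood at -0.85.

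By d4 the anterior forebrain list was lower in V1PAKI (10 measured, median -0.60, percentile 0, but -0.37 over all 17 fitted members), with SIX3 at 5.95 against 15.3 FPKM, FEZF1 at 17.1 against 38.2, HESX1 at 6.37 against 13.1 and LHX5 at 10.5 against 20.6. Neural progenitor genes were also lower (14 measured, -0.23, percentile 0.03, but -0.11 over all fitted members without the GC and length trend), while the endoderm median was higher (11 measured, 7 above 0 and 1 beyond 2-fold, 0.54, percentile 100, but 0.17 over all 17 fitted members), with APOA2, an apolipoprotein (11.7 against 4.07), and AFP (8.53 against 4.53). The nodal antagonists LEFTY2 (11.1 against 30.01) and LEFTY1 (16.5 against 34.8) were lower and UTF1 (51.5 against 31.0) was higher within a pluripotency list at 0.04 (20 measured, percentile 79.3). Other large differences were MAGEB17 (68.8 against 11.5), LCP1, an actin bundler (13.2 against 1.61), HHLA1 (14.3 against 2.24), ABHD12B (8.73 against 1.2), NLRP2 (0.20 against 14.7) and LRRC61 (0.0562 against 4.24). H19 (24.3 against 7.76) and NNAT (10.2 against 26.4) are imprinted genes that went opposite ways. With 222 of 13426 genes differing at least 2-fold (107 higher, 115 lower), d4 had the fewest, and TMEM189-UBE2V1, RAB4B-EGLN2, ARPIN-AP3S2, FMC1-LUC7L2 and URGCP-MRPS24 among the extremes are read-through names.

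At d10 V1PAKI held lower levels of most non-neural genes. COL1A1 (14.8 against 130 FPKM), COL3A1 (63.7 against 379), HAND1, a factor of lateral mesoderm (41.4 against 223), IGF2 (65.6 against 552), APOA1 (12.3 against 115), KRT8 (65.1 against 221), KRT19 (54.4 against 206) and CDX2 (0.176 against 3.45) were lower. Of the measured members, 10 of 16 mesoderm genes (median -1.35), 11 of 15 endoderm (-1.44), 8 of 15 trophoblast (-1.04), 6 of 12 non-neural ectoderm (-1.04) and 10 of 17 mesenchyme genes (-1.11) were at least 2-fold lower, each at percentile 0, with none 2-fold higher. WNT and BMP response (18 measured, -0.80, percentile 0.01), with BAMBI at 10.1 against 58.8, and endothelium (4 measured, -1.19, percentile 0.03) were lower too. Anterior forebrain genes were higher (14 measured, 0.66, percentile 100), with SIX3 at 76.3 against 32.5, FEZF1 at 84.9 against 39.5 and HESX1 at 40.6 against 6.53. MAP2, a dendrite protein (11.1 against 3.73), LIX1 (22.6 against 8.54) and ZNF521 (15.3 against 5.47) were higher, and HES5 (0.775 against 3.31), HOXB2 (0.866 against 8.03) and POU5F1 (62.7 against 134) lower. Further extremes were PTP4A1 (8.69 against 0.342), PHF6 (44.3 against 9.06), TDRD7 (13.5 against 2.37), ZNF280C (18.0 against 3.65), CST1 (4.03 against 54.6) and TMEM88 (19.1 against 186).

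In total 1596 of 14218 genes differed at least 2-fold at d10, 537 higher and 1059 lower, against 1482 higher and 1380 lower with TPM. GC content and length accounted for 43.1% of the variance of the d10 differences, and without that trend 694 genes differed. Over all fitted members the median without the trend was -1.09 for mesenchyme (-1.06 with it), -1.21 for mesoderm (-1.35), -0.90 for endoderm (-1.22), -0.86 for trophoblast (-1.0), -0.72 for non-neural ectoderm (-0.81) and -0.65 for endothelium (-0.85). For WNT and BMP response it was -0.52 (-0.80) and for anterior forebrain 0.47 (0.33).

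At d16D, the reverse of d10, non-neural genes were higher in V1PAKI. AFP, a protein of fetal liver and yolk sac (1242 against 226 FPKM), APOA1 (679 against 107), APOC3 (301 against 32.8), TTR (417 against 68.2), COL3A1 (701 against 102), POSTN (31.1 against 2.89), HAND1 (134 against 8.41), KRT19 (126 against 19.3), KDR (26.6 against 3.64) and H19 (405 against 39.7) were higher. Of the measured members, 14 of 15 endoderm genes (median 2.26), 11 of 11 trophoblast (1.75), 10 of 13 non-neural ectoderm (1.75), 12 of 18 mesenchyme (1.61), 13 of 16 mesoderm (1.35) and 13 of 19 pluripotency genes (1.15) were at least 2-fold higher, each at percentile 100. POU5F1 (34.2 against 5.64), TDGF1 (13 against 1.17) and L1TD1 (17.4 against 3.58) were among the last of these. Neural crest (20 measured, 0.92) with SOX10 at 10.0 against 0.557, midbrain and hindbrain (11 measured, 0.86) with HOXB2 at 10.7 against 1.80, and hypoxia (16 measured, 0.90) were higher at the same percentile.

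Ventral telencephalon, neuronal and neural progenitor genes were lower in V1PAKI at d16D, and the anterior forebrain list was lower by less (median -0.29 over all 17 fitted members). DLX1 (0.882 against 16.2 FPKM), DLX2 (1.96 against 12.1), DLX6-AS1 (0.119 against 11.8) and GSX2 (0.130 against 9.16) were lower, and 6 of 12 measured ventral telencephalon genes were at least 2-fold lower (median -0.97, percentile 0, but -0.38 over all 14 fitted members). In the neuron list 10 of 22 were (-0.90, percentile 0), with DCX, a protein of migrating neurons (4.89 against 26.0), CRMP1 (14.4 against 52.6) and TUBB3 (37.1 against 111), and ISLR2 (1.03 against 13.6) was lower as well. In the neural progenitor list 6 of 24 were (-0.57, percentile 0), with FABP7 (8.50 against 43.5), LHX2 (22.6 against 99.5) and HES5 (19.2 against 85.2), and Notch and proneural genes were lower (18 measured, -0.53, percentile 0.01). Dorsal genes went both ways (17 measured, -0.19, percentile 21.7, and -0.04 over all 15 fitted members), with WNT8B at 32.7 against 12.9 and EMX2 at 12.3 against 24.2. In all, 1362 of 15194 genes differed at least 2-fold, 836 higher and 526 lower, against 1410 and 1324 with a pseudocount of 0.1, 1358 and 1178 with TPM and 947 and 375 with median-of-ratios scaling.

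At d16V non-neural genes were lower in V1PAKI. COL3A1 (3.44 against 161 FPKM), COL1A1 (1.65 against 44.8), LUM, a matrix proteoglycan (1.12 against 40.2), IGF2 (6.44 against 170), AFP (4.88 against 132), FGA (0.174 against 19), HAND1 (0.734 against 19.9) and CDH1 (1.36 against 10.3) were lower. Of the measured members, 10 of 17 mesenchyme genes (median -1.63), 9 of 13 endoderm (-1.59), 7 of 11 non-neural ectoderm (-1.25), 6 of 11 mesoderm (-1.01) and 4 of 14 pluripotency genes (-0.42) were at least 2-fold lower, each at percentile 0. Over all 16 fitted members the mesoderm median was -0.54, and -0.40 without the GC and length trend, and the pluripotency median without it was -0.27. Ventral telencephalon genes were lower by less (14 measured, 1 beyond 2-fold, -0.52, percentile 0), with NKX6-2 at 4.75 against 16.3, OLIG1 at 8.24 against 15.4 and NKX2-1 at 44.8 against 67.5. Notch and proneural genes stood at -0.40 (17 measured, percentile 0, and -0.27 without the trend). In the hedgehog response list (13 measured, 0.16, percentile 100) SHH was at 4.23 against 12.2, while PTCH1 (73.2 against 65.3), GLI1 (13.2 against 11.6) and FOXA2 (11 against 8.12) were higher. Neural progenitor genes centred at -0.00 (23 measured, percentile 65.2, and 0.12 with median-of-ratios scaling), with ZIC1 at 2.31 against 6.43, HES5 at 30.9 against 46.4 and SOX3 at 135 against 90.8. SOX21 (65.2 against 30.3), TIGD1 (4.99 against 0), TOMM6 (7.14 against 0.822), SLC39A1 (28.0 against 7.20) and TDRD7 (11.4 against 3.18) were higher, as were the read-through names URGCP-MRPS24 and BIVM-ERCC5. For TIGD1 and SLC39A1 the Ctrl d16V library stood apart, since all other libraries held at least 1.92 and 26.8 FPKM. In total 423 of 14569 genes differed at least 2-fold, 60 higher and 363 lower.

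**Figure D3:**
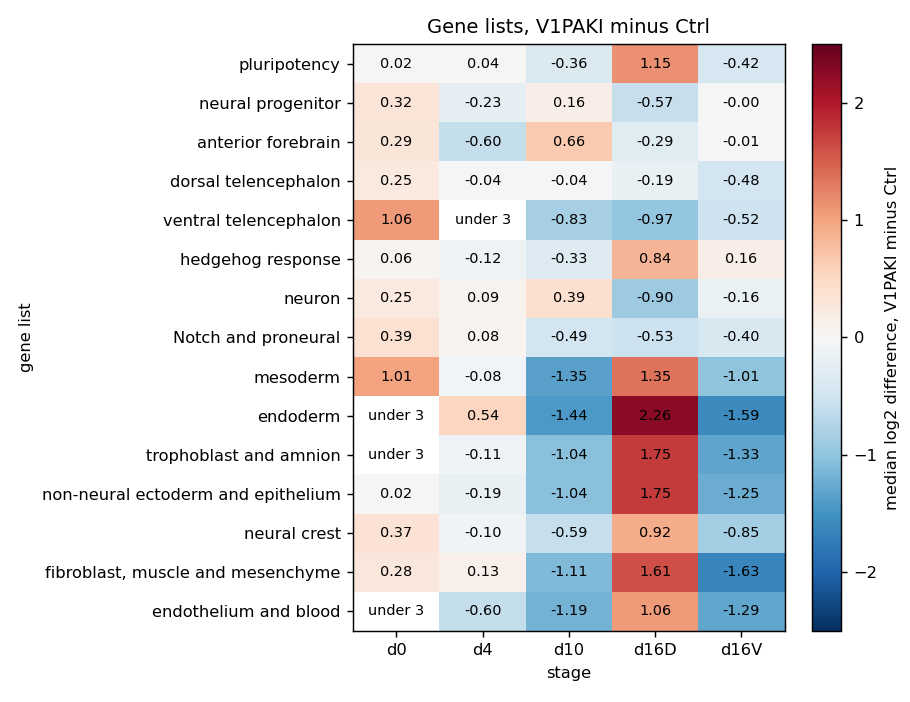
Median log2 difference (V1PAKI minus Ctrl) of the cell type lists at each stage. Lists with under 3 measured members are marked, and the endoderm list stood at -1.44 at d10, 2.26 at d16D and -1.59 at d16V.

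Single-stage counts depended on the settings where values were low. A pseudocount of 0.1 gave 1397, 563, 3092, 2734 and 1043 genes from d0 to d16V, TPM gave 1047, 460, 2862, 2536 and 880, and a filter at 5 FPKM gave 365, 86, 746 and 168 at d0, d4, d16D and d16V. Differences of HAND1, COL3A1 and the other non-neural genes ran opposite ways between stages. Across all genes the d10 differences correlated at 0.34 with those of d16V, -0.32 with those of d16D and -0.35 with those of d0. Without the GC and length trend these correlations were 0.42, -0.40 and -0.15. By correlation of all genes, V1PAKI was closest to Ctrl of the same stage at d0 (0.965), d4 (0.983) and d16V (0.969). V1PAKI d16D was closer to Ctrl d10 (0.939) than to Ctrl d16D (0.923), and V1PAKI d10 was closer to Ctrl d4 (0.921) than to Ctrl d10 (0.917), though the latter turned after removal of the GC and length trend (0.952 for Ctrl d10, 0.934 for Ctrl d4). The share of FPKM from mitochondrial genes ran from 14.3% in V1PAKI d16D to 24.2% in Ctrl d0.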

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

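All tests of SOX1 and of chromosomes 17 and 10 in this part were chosen after the result was seen. For 10 of the 27 lists compared, the change from d16D to d16V went one way in V1PAKI and the other way in Ctrl by a median beyond 0.2 in each, which drew attention to them, and this difference between the lines was not tested, since each rests on 1 library per arm. Of the non-neural lists, 4 were lower at d16V in V1PAKI and higher in Ctrl: the median was -1.94 in V1PAKI and 0.24 in Ctrl for mesoderm, with KDR and HAND1 among its members, -2.83 and 0.30 for non-neural ectoderm, -2.09 and 0.58 for mesenchyme and -1.87 and 0.31 for endothelium. Lower in both lines were endoderm (-3.22 and -0.47), neural crest (-1.85 and -0.16) and trophoblast (-2.11 and -0.10). Pluripotency genes such as POU5F1 stood at -1.21 and 0.86, hypoxia genes at -0.58 and 0.23 and stress genes at -0.62 and 0.28. Neural lists went the opposite way, at 0.31 in V1PAKI and -0.62 in Ctrl for neural progenitor, 0.53 and -0.43 for anterior forebrain and 0.47 and -0.40 for neuron. The members behind each median had at least 1 FPKM in either arm of that line, so the sets differ between the lines. Over a fixed set of 47 mesoderm, endoderm and mesenchyme genes the median log2 level went from 1.67 at d16D to 2.02 at d16V in Ctrl and from 3.22 to 0.69 in V1PAKI. Of 37 groups of 5 values tested, on library totals and shares, list medians, the 3 title genes and both chromosome segments, 2 had a value far from the rest. That is about the 1 in 20 that chance alone gives. These groups were the chromosome segments, which were included because they had already stood out at d0, so the outcome is no separate support for them. Both were of the V1PAKI d0 library, whose step at 40 Mb of chromosome 17 stood at 0.39 and whose genes from 120 to 130 Mb of chromosome 10 stood at -0.62 against the median of all libraries.

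SOX1 was lower in V1PAKI at both day 16 arms, by -1.49 at d16D and -1.23 at d16V on the log2 scale. A smaller share of neural progenitors in the library is argued against at d16V, where the median of the other 23 progenitor genes was -0.0013 and none was lower than SOX1 (ZIC1, at -1.17, came nearest). At d16D the same explanation stays open, since the other 23 stood at -0.52, 3 of them (FABP7 the lowest, at -2.23) were lower than SOX1, and non-neural genes were higher at a median of 1.56. Scaling is argued against, as SOX1 was over 2-fold lower in both arms under all 3 scalings tried. A lower SOX1 level tied to the V1PAKI line is a candidate explanation at d16V, but with 1 line per genotype an effect of the edit and of the line's history could not be separated.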

How the results depend on the processing

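With 1 library per line and stage, no paired analysis of repeated cultures was possible, and a lone library left after an omission is assumed to vary like the others. Depth is unknown, so the counting error of low genes such as SOX1-OT could not be given. Leaving out chromosome 17 at d0, removing the GC and length trend and leaving each stage out of the means of SOX1-OT, SOX1 and HDAC10 were chosen after seeing the data. Of 119 alternatives to the main results, omissions of single libraries or stages not counted, 75 kept the direction or stayed within 1.5 times and 44 moved. Of 1273 for single genes, 1010 kept direction and side, 262 kept direction but no longer passed (259 of them within 1.5 times of the main log2 value, 0 smaller, 3 larger) and 1 turned (HDAC10).

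From d0 to d16V, a pseudocount of 0.1 gave 1397, 563, 3092, 2734 and 1043 genes at least 2-fold apart and TPM gave 1047, 460, 2862, 2536 and 880, since a smaller pseudocount, or larger values against it, spreads low genes. A filter at 5 FPKM, which keeps fewer genes, gave 365, 86, 746 and 168 at d0, d4, d16D and d16V. Without the GC and length trend there were 384 at d0 and 694 at d10. For d4 against d0 the calls were 11 with no filter, 59 at 5 FPKM, 79 with TPM, 222 without the trend and 237 with no genotype block. For d10 against d4 they were 3 with no filter, 629 without the trend and 408 with no block. For d16D against d10 they were 91 with a pseudocount of 0.1, 34 with no filter, 82 at 5 FPKM, 333 without the trend and 244 with no block. For d16V against d10 they were 64 with no filter, 194 with quantile normalization and 277 with no block, and for d16V against d16D 7 with a pseudocount of 0.1, 2 at 5 FPKM and 18 with TPM. The genotype effect had 0 genes with no filter, at 5 FPKM and with both day 16 arms averaged. With an estimated correlation 0 lists passed in all 6 comparisons, against 2, 11, 12, 14, 16 and 13. Except where the construction shows it, the cause was not tested.

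Leaving out 1 library or stage in turn gave 0 to 3 genes for genotype, 0 to 2 for d4 against d0, 0 to 124 for d10 against d4, 29 to 384 for d16D against d10, 16 to 55 for d16V against d10 and 5 to 101 for d16V against d16D. The mean differences ran from -0.57 to -0.26 for SOX1-OT, from -0.88 to -0.49 for SOX1 and from -0.27 to 0.05 for HDAC10, which turned to 0.045 without d10.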

Other observations

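In this part, the tests of the share of X-linked genes, of their scaling and of a line difference, the test of the d10 count and the GC test of chromosome 17 were chosen after the result was seen. COL3A1 ran differently along the course of each line: 0, 6.32, 379, 102 and 161 FPKM in Ctrl from d0 to d16V, and 0, 9.48, 63.7, 701 and 3.44 in V1PAKI. H19, an imprinted growth-linked RNA, ran at 0.441, 7.76, 434, 39.7 and 149.8 FPKM in Ctrl and at 0.987, 24.3, 102, 405 and 9.23 in V1PAKI. SOX17, a factor of endoderm, stood at 5.69 FPKM in Ctrl and 0.841 in V1PAKI at d10, and at 0.575 and 7.17 at d16D. Over 47 non-neural genes the median log2 level was 3.4 in Ctrl and 1.83 in V1PAKI at d10, 1.67 and 3.22 at d16D, and 2.02 and 0.69 at d16V.

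Among broadly expressed neural genes, SOX2 stood at 206 FPKM in Ctrl and 246 in V1PAKI at d16V, and at 130.2 and 83.8 at d16D. NES, an intermediate filament of progenitors, was at 202 and 203 at d16V. HDAC1 lay between 24.1 and 38.3 FPKM in all 10 libraries, and HDAC5 stood at 13.7 in Ctrl and 6.19 in V1PAKI at d16D. Of genes on the X chromosome, AIFM1 (0.83 over the 5 stages, adjusted p = 0.392), EIF1AX (1.02, 0.599), HPRT1 (0.85), TSPAN6 (0.84) and MAGEH1 (0.70), chosen after their values were seen, were higher in V1PAKI in 5 of 5 pairs without passing.

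Chromosome-scale differences between the lines were of 2 kinds. Of 161 genes higher in V1PAKI at an unadjusted p below 0.05, 51 were X-linked (31.7%, against 3.61% of genes tested). The share stood at 21.4% without the GC and length trend (65 of 304 genes) and at 26% under median-of-ratios scaling (52 of 200). This argues against both as the whole cause of the share. Its fall came with more higher genes in total and not with fewer X-linked ones. The median of all X-linked genes decided nothing here, since it lay over 0.1 above the autosomal median in only 1 stage both as deposited and without the trend. By 10 Mb bins without the trend, the X bin starting at 10 Mb was higher in V1PAKI at every stage (0.103, 0.262, 0.499, 0.306 and 0.221 from d0 to d16V). At d4, d10, d16D and d16V it was the highest bin outside chromosome 17. The other X bins scanned went both ways between stages, such as that starting at 100 Mb (0.115, 0.153, 0.297, -0.0915 and 0.17). A difference of X-linked expression between the lines stays open. As deposited 61.7% of 569 X-linked genes lay above the autosomal median, more than of any autosome, but without the trend 59.9% did, against 61.5% on chromosome 17, and the camera call (adjusted p = 4.27e-05) was lost with an estimated correlation (0.999). In the V1PAKI d0 library alone, distal chromosome 17 was higher and distal chromosome 10 lower, and this is neither a GC and length trend, as the step at 40 Mb of chromosome 17 stood at 0.45 without it, nor a difference of the Ctrl d0 library, which showed -0.072 on chromosome 17 and 0.072 from 120 to 130 Mb of chromosome 10. An extra copy of distal 17 in part or all of the cells could give the 0.55 seen among 148 distal genes of at least 10 FPKM, 97.3% of them above 0, and a loss of distal 10 could give the -0.50 found beyond 130 Mb. ZNF558 and ZNF542P were listed at 0 in this library as in the other V1PAKI libraries, and why the later ones lack both segments was not tested.

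The count of genes at least 2-fold apart at d10 may in part reflect a GC and length trend of single libraries, which accounted for 43.1% of the variance of the differences against 16.8% at d0 and 2.52% or less at the other stages. It does not account for the lower mesenchyme genes, whose median over the same 18 genes stood at -1.09 without the trend and -1.06 with it. A different cell mixture of the V1PAKI d10 culture remains open and was not tested.

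For the genotype effect, 3 of 100 drawn splits of the 10 libraries, of 126 possible, called as many genes as the real split with its 3 genes (ZNF558, ZNF542P and ZNF619), the real one included, but splits that leave pairs together carry less of the line difference, and those that part all 5 pairs are too few for a share under 0.05. The others of these 3 called 474 genes each. They are the same contrast with the sides exchanged, since pairs left together drop out of a fit blocked by stage. The drawn splits are therefore not all separate groupings, and 3 of 100 is not a share of independent alternatives. That contrast parts the libraries of d10 and day 16 as the levels of COL3A1 do, but which genes it called was not examined. Of 9 drawn splits that part all 5 pairs, the others called 0, and so did the split that exchanges the d16D libraries of both lines with each other.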
